A study of Homo sapiens with 4 samples.

How the data were processed

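Total RNA of NCI-H209 and Lu139 cells, electroporated with control or TTF-1 siRNA, was extracted with a column kit, converted to biotin-labelled cRNA and hybridised to Affymetrix arrays, per the labels' protocols. The deposited values are probe set intensities on a linear scale, 1 column per array, with no value below 3.03 and the highest at 26148. Affymetrix Expression Console is named in the submitters' processing notes. Its version, the summarisation algorithm, the normalization and the genome build are not given in the sources used here. From the values themselves, 2416 probe sets had exactly equal intensities on the 2 arrays of NCI-H209 and 2206 on the 2 arrays of Lu139, against 0 for any pair of arrays of different lines. The lower quartiles of the arrays of a line were also close (19.5 and 19.9 in NCI-H209, 17.5 and 17.8 in Lu139). The upper quartiles differed more within a line, at 263 and 252 in NCI-H209 and 189 and 183 in Lu139. Values normalized separately for each line could show such exactly equal intensities. That would leave comparisons within a line usable and make small differences between lines depend on the scaling.

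Of the 54675 probe sets, 62 were array controls and were left out of gene values, 41091 were paired with exactly 1 gene symbol in the platform's annotation, 1801 with several and 11721 with none. Symbols were updated by gene identifier through a RefSeq gene table of the assembly GRCh38.p14, which matched 41037 probe sets and was used for names alone. No coordinates are given. A gene's value was that of its probe set with the highest mean log2 intensity over the 4 arrays, and 19775 genes had a value. Some genes of the fixed set had no probe set paired with exactly 1 symbol and are not analysed here. Expression was taken as log2(value + 18.7), with the 25th percentile of all values as pseudocount. A gene was kept in a line where its mean over the 2 arrays of that line exceeded 5.80 (the 40th percentile of the mean log2 value over all probe sets, an intensity of 37.0). This left 14632 genes in NCI-H209, 13996 in Lu139 and 13306 in both. The test across lines used the 14547 genes whose mean over all 4 arrays passed the limit.

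With 1 array per group, differences within a line were given by size, with a threshold of 2-fold, and have no test. The effect across lines was tested with limma (version 3.58.1, R version 4.3.3) on a model with terms for line and siRNA, a trend of the variance on intensity, 1 residual degree of freedom and 5.91 prior degrees of freedom, with Benjamini-Hochberg adjustment. All tests were two-sided. The line is a block in this model because both arrays of a line come from the same cell line, and the spread is the difference of the siRNA effect between the lines. The line coefficient of the same model gave the comparison of Lu139 with NCI-H209. Its p-values, like those of the siRNA effect in limma, measure only the spread between these 4 arrays, which may be technical. Gene lists were tested with camera of limma with a preset correlation of 0.01 between genes, adjusted over 32 lists. With the preset, camera sets the genes of a list against all other tested genes. Its p then rests on the spread over genes and not on replication between arrays or lines. An estimated correlation was the alternative, and there camera reads its statistic on the 1 residual degree of freedom. For the histone list the estimate was 0.011, near the preset 0.01, yet the camera p went from 4.62e-04 to 0.178. That alternative therefore cannot decide whether correlation between genes accounts for a call. Other passing lists had estimates further from the preset. These were 0.242 for the unfolded protein and ATF4 response, 0.126 for DNA replication and G1/S and 0.067 for mitosis and G2/M. Oxidative phosphorylation had 0.022 and immediate early genes -0.037. Where the estimate is above the preset, the camera p with the preset may be too small. In each line a list's median was set against 10000 random lists of the same size, matched on mean expression in 20 bins, as a description of the arrays. Members of a list were also adjusted over that list alone. The figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

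The procedure was tested on simulated arrays of the siTTF-1 comparison with 14547 genes. Each simulated change had the same size in both lines, and noise was drawn independently for each gene from the fitted spread. At an adjusted p under 0.05 it recovered 21.1% of genes changed by 0.5 on the log2 scale, 94.8% of those changed by 1 and 100% of those changed by 2, with 8 false calls. The list shifted in the simulation was the 1 list called. Recovery of changes that differ in size between the lines, as that of RCN1 did (-1.80 and -1.23), was not simulated.

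The design, the gene lists, the thresholds and the rule for the genes named in the text were fixed before the data were examined. Not every gene that the rule took is named in the text. The rule took NKX2-1 with all its probe sets, the 12 lowest and 12 highest genes moving the same way in both lines by the smaller of the 2 log2 fold changes, the 6 lowest and 6 highest in each line, up to 4 members of each list with the largest mean change, the 10 lowest and 10 highest between the lines, and a fixed set of genes of lung, neuroendocrine and apoptotic interest. Genes beyond this rule, such as the members of a list that passed adjusted over the list alone, HSPA5, HSP90B1, CALR, CDK1, CCNB1, CCNE1, MDM2, BAX and the antioxidant genes of the closing section, were chosen after their values were seen. Alternatives were a halved and a doubled pseudocount, quantile and cyclic loess normalization over the 4 arrays, the mean of all probe sets of a gene, probe sets without the _x_at suffix, no expression limit and one at the 60th percentile, no variance trend, no line term, thresholds of 1.5-fold and of 0.1 for the adjusted p, and the estimated correlation. Chosen after seeing the data were quantile normalization within each line, removal of each line's trend on mean signal and centring of each array on its median.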

Results

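Transcript levels were measured on 4 Affymetrix arrays in a pair of human small cell lung cancer lines, NCI-H209 and Lu139. Each line was electroporated with a non-targeting control siRNA (siNTC) or with siRNA against TTF-1 (siTTF-1), the homeodomain transcription factor of lung and thyroid that is encoded by NKX2-1. Each of the 4 combinations of line and siRNA was measured on 1 array, so a value within a line has no replicate, and the 2 lines are the only replication of the siRNA effect. The small number of arrays limits the precision of every value. The median probe set intensity was 56.6 and 57.7 on the control and siTTF-1 arrays of NCI-H209, and 48.4 and 49.6 on those of Lu139. Fold changes below are siTTF-1 over siNTC on the log2(value + 18.7) scale, which understates the change of dim genes.

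The targeted transcript was measured first. NKX2-1 was lower after siTTF-1 in both lines and on both of its probe sets. On the brighter probe set, 211024_s_at, the intensity was 596 in control NCI-H209 cells and 243 after siTTF-1, 40.7% of control. In Lu139 it was 780 and 461, 59.1% of control. On 210673_x_at the siTTF-1 level was 64.6% of control in NCI-H209 and 55.3% in Lu139, so the probe sets differed on which line had the deeper decrease. By the brighter probe set, NKX2-1 had the log2 fold change ranked 47 from the lowest of 14632 genes above the expression limit in NCI-H209 and 59 of 13996 in Lu139. Its mean log2 fold change was -0.98 (SD 0.35, n = 2 lines). The limma 95% confidence interval was -1.31 to -0.66, with a limma adjusted p of 0.0844 over all genes. That interval borrows 5.91 prior degrees of freedom from other genes beside 1 residual degree of freedom, so the 2 lines alone give less precision.

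**Figure D1:**
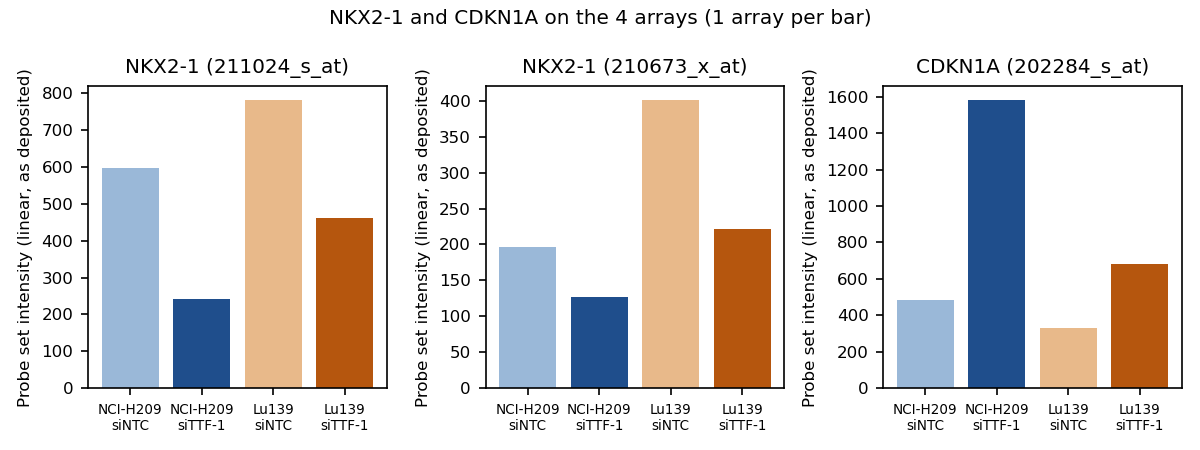
Linear probe set intensity, as deposited, of the 2 NKX2-1 probe sets and of CDKN1A on the 4 arrays, with each bar 1 array and no error bar because groups hold 1 array. NKX2-1 on 211024_s_at was 596 and 243 in NCI-H209 and 780 and 461 in Lu139, and CDKN1A was 483 and 1580 in NCI-H209 and 329 and 681 in Lu139.

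The series asks which genes TTF-1 regulates in small cell lung cancer lines. Genes at least 2-fold lower after siTTF-1 in both lines were RCN1, which encodes a calcium-binding protein of the endoplasmic reticulum, MAP7D2, which encodes a microtubule-associated protein, and TRIM24, which encodes a chromatin-binding transcriptional co-regulator. RCN1 had log2 fold changes of -1.80 in NCI-H209 and -1.23 in Lu139, a mean of -1.51 (SD 0.40, n = 2 lines). MAP7D2 had -2.04 and -1.12 (mean -1.58, SD 0.66), and TRIM24 had -1.53 and -1.02 (mean -1.28, SD 0.36). As the mean of all its probe sets TRIM24 had -1.01 and -0.60 and was not 2-fold lower in Lu139. The next lowest genes in both lines were NAB1, a co-repressor of EGR transcription factors (-1.27 in NCI-H209 and -0.95 in Lu139), and KRCC1 (-1.61 and -0.93). ELOVL2, an elongase of polyunsaturated fatty acids, had -0.97 and -0.92, and SAMHD1, a deoxynucleotide triphosphate hydrolase, had -1.56 and -0.92. Below them came DSE (-1.38 and -0.91), FGD3 (-1.09 and -0.87), the endoplasmic reticulum cation channel gene TMEM38B (-1.22 and -0.80), the neural adhesion gene NTM (-0.81 and -0.77) and the splicing factor gene MBNL3 (-1.22 and -0.77, at 36.1 after siTTF-1 in Lu139, just under the expression limit of 37.0). RCN1 and MAP7D2 were each read by 1 probe set, so the mean of all probe sets could not change their values. All 6 probe sets of SAMHD1 were lower in both lines. TRIM24 and NAB1 were lower on 3 of their 4 probe sets in each line, and DSE on 2 of 4 in NCI-H209 and 1 of 4 in Lu139.

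CDKN1A, which encodes the cyclin-dependent kinase inhibitor p21, was the gene at least 2-fold higher after siTTF-1 in both lines. Its intensity was 483 and 1580 in NCI-H209 and 329 and 681 in Lu139, log2 fold changes of 1.67 and 1.01 (mean 1.34, SD 0.47, n = 2 lines). The value in Lu139 lies at the threshold: a doubled pseudocount gave 1.64 and 0.97, so that 0 genes were 2-fold higher in both lines, and quantile normalization over the 4 arrays gave 2 such genes, CDKN1A (1.70 and 1.03) and WASF3 (1.25 and 1.0). WASF3, a regulator of actin assembly, followed with 1.21 and 0.97, then REEP3 (1.22 and 0.82), SYBU, which encodes the kinesin adaptor syntabulin (0.79 and 0.89), and AQP3, a water and glycerol channel (1.66 and 0.77). Next by the smaller of the 2 values were GNB4 (0.76 and 0.67), UGT8, an enzyme of galactosylceramide synthesis (1.04 and 0.58), SYTL1 (0.69 and 0.58), CLN8 (0.74 and 0.58), FRMD8 (0.75 and 0.57), FRMD3 (0.57 and 0.64) and the aldo-keto reductase gene AKR1C3 (0.56 and 0.78). CDKN1A and WASF3 were each read by 1 probe set, so no other probe set could bear out their values.

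Over the 14547 genes tested across both lines, limma called 0 genes lower and 0 higher at an adjusted p under 0.05. The smallest adjusted p was 0.0713, shared by RCN1, MAP7D2, TRIM24, CDKN1A and WASF3 among others, and at an adjusted p under 0.1 there were 39 lower and 8 higher genes. At an unadjusted p under 0.05, limma gave 1345 lower and 1052 higher genes, where 727 in all would be expected with no effect. The log2 fold changes of the 2 lines correlated across the 13306 genes above the expression limit in both (Pearson r = 0.519, Spearman rho = 0.466), and 65.2% of these genes had the same direction. Genes are not independent replicates, so these describe the arrays. At 1.5-fold, 50 genes were lower and 6 higher in both lines, where independent lists of the same sizes would share 4.0 and 0.270, and 0 genes passed 1.5-fold in opposite directions. The count of calls depended on the scaling: quantile normalization over the 4 arrays gave 93 lower and 32 higher genes at an adjusted p under 0.05 in limma, and quantile normalization within each line gave 33 and 8. An expression limit at the 60th percentile gave 32 and 6 in limma.

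**Figure D2:**
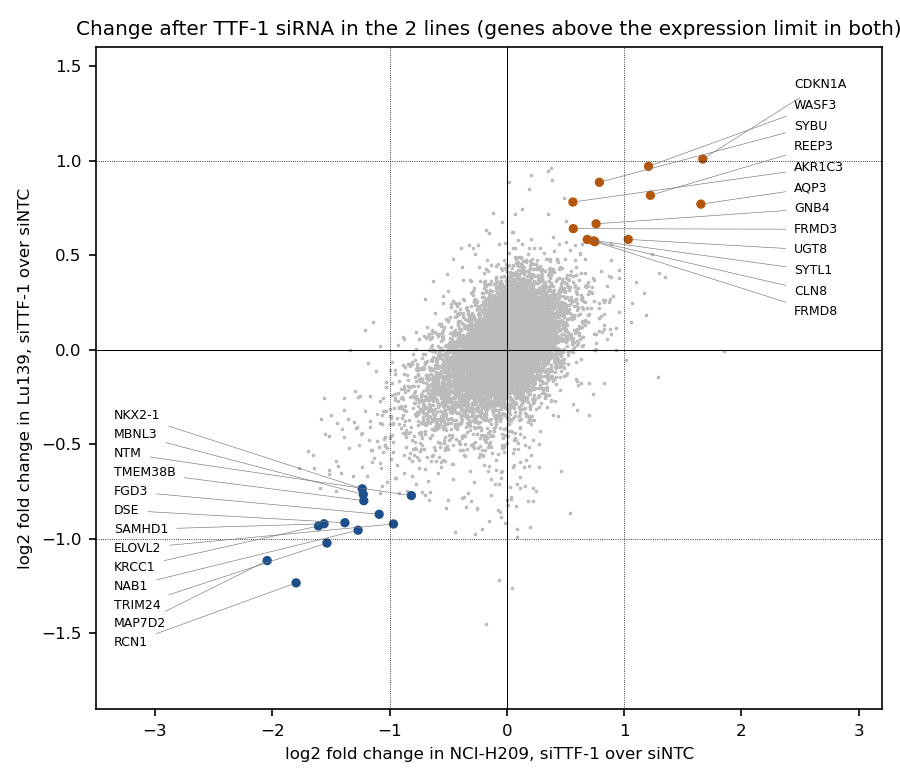
Log2 fold change (siTTF-1 over siNTC) in Lu139 against that in NCI-H209, with each grey point 1 of the 13306 genes above the expression limit in both lines, 1 array per group, and dotted lines at 2-fold. Coloured points are NKX2-1 and the 12 lowest and 12 highest genes that moved the same way in both lines, from RCN1 at -1.80 and -1.23 to CDKN1A at 1.67 and 1.01.

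Within NCI-H209, 95 genes were at least 2-fold lower and 23 at least 2-fold higher after siTTF-1, or 43 and 13 with the mean of all probe sets per gene. The lowest was RBM47, an RNA-binding splicing regulator, whose intensity was 1426 in control cells and 235 after siTTF-1 (log2 fold change -2.51) and whose 5 probe sets were all lower. In Lu139 RBM47 was near background, at 15.9 and 13.9. Other low genes in NCI-H209, beyond MAP7D2 and RCN1, were TMTC4 (-1.77), the cation channel gene TRPA1 (-1.70) and NSRP1 (-1.65). The highest was NID1, which encodes the basement membrane protein nidogen-1, at 189 and 949 (log2 fold change 2.22), followed by the transcription factor gene MAF at 41.6 and 199 (1.85). Next to CDKN1A and AQP3, RAB8B (1.35) was also high in this line, as was SPRR1B, at 35.1 on the control array, under the expression limit of 37.0, and 125 after siTTF-1.

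Within Lu139, 6 genes were at least 2-fold lower and 1 at least 2-fold higher. These small counts depended on the settings: 10 were lower with a halved pseudocount and 3 with the mean of all probe sets per gene, while 0 were higher with a doubled pseudocount and 2 with quantile normalization, over the 4 arrays or within each line. The lowest were COPG2IT1 (-1.45), CDK13 (-1.26), RCN1 (-1.23), the inositol trisphosphate receptor gene ITPR2 (-1.22), MAP7D2 (-1.12) and TRIM24 (-1.02). CDK13 was read here from 232266_x_at, and its mean log2 fold change over the 2 lines was -0.61 on that probe set but -0.12 as the mean of its 7 probe sets. ITPR2 was lower on all 4 of its probe sets in Lu139, where its intensity was 109 in control cells and 36.4 after siTTF-1, just under the expression limit. After CDKN1A and WASF3, the highest genes in Lu139 were AKR1C2 (0.96), the kisspeptin receptor gene KISS1R (0.94), the neuropeptide gene ADCYAP1 (0.93) and AKR1C1 (0.90). AKR1C1 and AKR1C2 are near-identical paralogs read here by probe sets that can cross-hybridise, so their values are not independent. The log2 fold changes had an SD over genes of 0.272 in NCI-H209 and 0.186 in Lu139. Whether a gene's effect differed between the lines was not tested, because each line has 1 array per siRNA.

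Of the 32 gene lists fixed before the data were examined, 6 passed camera at an adjusted p under 0.05, 3 of them downward. As a baseline for the list medians here and below, genes above the expression limit in both lines had a median log2 fold change of 0.008 in NCI-H209 and 0.034 in Lu139. The camera p-values with the preset correlation rest on the spread over genes, not on replication between the lines. Those with an estimated correlation, here and below, rest on 1 residual degree of freedom. The latter cannot decide whether correlation between genes accounts for a call. Genes of mitosis and G2/M fell as a list (camera adjusted p = 2.06e-06, or adjusted p = 0.738 with an estimated correlation). The median log2 fold change over its 40 genes was -0.13 in NCI-H209 and -0.09 in Lu139, at percentiles 0.19 and 0.01 of matched random lists. In this list, 26 genes were lower and 2 higher in both lines, and 8 fell and 0 rose in limma adjusted over the list alone, against 0 over all genes. BIRC5, the survivin gene that is needed for chromosome segregation, had -1.02 and -0.70. HMMR had -0.73 and -0.24, the kinetochore gene CENPF -0.48 and -0.31, and TOP2A, a DNA topoisomerase, -0.45 and -0.32. The others of the 8 were NDC80, PRC1, NUF2 and ASPM. CDK1 had 0.01 and -0.02, and CCNB1 had -0.03 and -0.06.

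Genes of DNA replication and G1/S fell as a list (camera adjusted p = 7.28e-04, or adjusted p = 0.738 with an estimated correlation). Of its 39 tested genes, 24 were lower and 7 higher in both lines, and 0 passed limma adjusted over the list alone or over all genes. Its medians were -0.16 in NCI-H209 and -0.06 in Lu139. The DNA polymerase alpha subunit POLA1 had -0.63 and -0.34, GINS4 -0.60 and -0.36, CLSPN -0.77 and -0.08, and MCM10 -0.63 and -0.21, while the G1/S cyclin CCNE1 had 0.63 and 0.19. Histone genes fell as a list too (camera adjusted p = 0.0037, or adjusted p = 0.738 with an estimated correlation), with 10 of 14 tested genes lower and 1 higher in both lines. Their medians were -0.16 and -0.13. H2BC12 fell in limma adjusted over the list alone (log2 fold changes -0.54 and -0.37), the 1 histone gene of which this held, and 0 passed over all genes. H2BC9 had -0.69 and -0.25, and H2AC6 -0.38 and -0.29. Probe sets of the histone clusters can cross-hybridise.

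The unfolded protein and ATF4 response rose as a list (camera adjusted p = 4.99e-04, or adjusted p = 0.738 with an estimated correlation). The median over its 33 genes was 0.24 in NCI-H209 and 0.06 in Lu139, at percentiles 100 and 91.9. In both lines 19 genes were higher and 4 lower, and 7 rose and 0 fell in limma adjusted over the list alone, against 0 over all genes. The 7 were SLC3A2 (0.89 and 0.39) and SLC7A5 (0.81 and 0.42), the subunits of an amino acid transporter, TRIB3 (0.51 and 0.68), the transcription factor genes DDIT3 (0.62 and 0.51), ATF3 (0.63 and 0.40) and CEBPB (0.50 and 0.57), and DDIT4, an inhibitor of mTORC1 signalling (0.72 and 0.31). Of the other members, HSPA5 had 0.03 and -0.02, HSP90B1 0.07 and -0.12, and CALR 0.02 and -0.15.

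Immediate early genes rose as a list (camera adjusted p = 0.0166, or adjusted p = 0.738 with an estimated correlation), with 16 of 27 tested genes higher and 4 lower in both lines and medians of 0.10 and 0.08. The transcription factor gene KLF4 rose in limma adjusted over the list alone (0.49 and 0.80), with 0 genes over all genes. PHLDA1 had 0.83 and 0.19, FOS 0.60 and 0.22, and KLF6 0.49 and 0.33. Oxidative phosphorylation genes rose by small amounts as a list (camera adjusted p = 0.0349, or adjusted p = 0.738 with an estimated correlation). Their medians were 0.07 in NCI-H209 and 0.08 in Lu139, 25 of 36 were higher and 5 lower in both lines, and 0 passed limma over the list alone or over all genes. The largest mean change in the list went against its direction, that of UQCRB, of complex III, with -0.44 and -0.12. NDUFB5, of complex I, had 0.28 and 0.19, ATP5MC1 0.19 and 0.22, and SDHC, of complex II, 0.24 and 0.16. The oxidative phosphorylation call was lost under 7 alternatives besides the estimated correlation, with a camera adjusted p from 0.00762 to 0.364 over the other alternatives. The immediate early call was lost with the mean of all probe sets per gene (camera adjusted p = 0.0873) and with no line term (0.18), within a range from 0.0102 to 0.18.

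**Figure D3:**
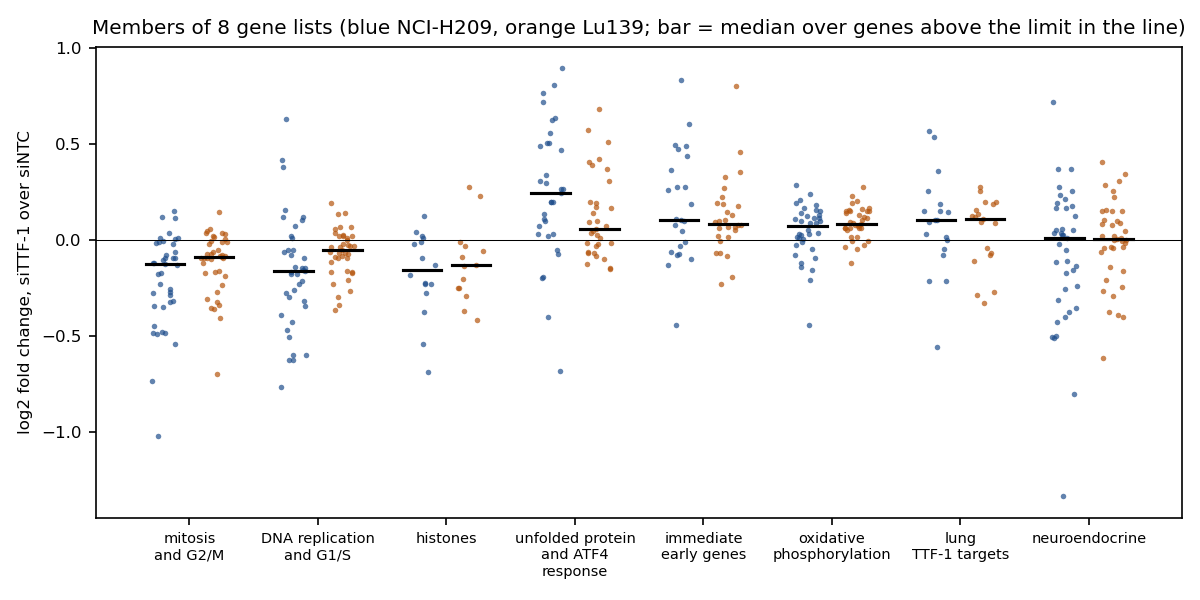
Log2 fold change (siTTF-1 over siNTC) of each member above the expression limit of the line in 8 gene lists, blue for NCI-H209 and orange for Lu139, with 1 array per group and a bar at the median over genes. The medians of mitosis and G2/M genes were -0.13 and -0.09, those of the unfolded protein and ATF4 response 0.24 and 0.06, and those of lung TTF-1 targets 0.10 and 0.11.

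Lung epithelial genes known as TTF-1 targets did not pass as a list (camera adjusted p = 0.344). Their medians were 0.10 in NCI-H209 and 0.11 in Lu139, 3 of the 21 tested genes were lower and 10 higher in both lines, and 0 passed limma adjusted over the list alone or over all genes. The surfactant genes SFTPB (0.01 and -0.04) and SFTPC (0.10 and 0.19) and the aspartic protease gene NAPSA (0.03 and 0.25) had small values, and the secretoglobin gene SCGB3A2 was below the expression limit. LMO3 had -0.56 and -0.11, LAMP3 -0.21 and -0.33, SELENBP1 0.36 and 0.20 (at 34.2 on the control array of Lu139, under the expression limit), and MUC1 0.53 and 0.08. Among lung and foregut transcription factors (camera adjusted p = 0.942 over 21 genes), NFIB fell (-1.06 and -0.54) and CEBPB rose (0.50 and 0.57) in limma adjusted over the list alone, with 0 over all genes. NFIB was lower on 6 of 9 probe sets in NCI-H209 and 8 of 9 in Lu139. FOXA1 had -0.44 and 0.03 and FOXA2 -0.33 and 0.20.

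Neuroendocrine genes, which mark the secretory and neuronal phenotype of most small cell lung cancers, did not pass as a list (camera adjusted p = 0.405), with 14 of 39 tested genes lower and 15 higher in both lines. TAGLN3 fell in limma adjusted over the list alone (-0.43 and -0.40), the 1 gene of which this held, against 0 over all genes. GFI1 had -0.51 and -0.39. DDC, the aromatic amino acid decarboxylase gene, had -1.34 in NCI-H209 and 0.00 in Lu139, and the granin gene SCG2 had -0.81 and -0.06, while the calcitonin gene CALCA had 0.72 and 0.22. INSM1 (-0.31 and 0.00), CHGA (0.16 and 0.30), SYP (-0.11 and 0.07), NCAM1 (-0.35 and -0.16) and DLL3 (-0.38 and 0.00) had values of mixed sign or small size, and REST, a repressor of neuronal genes, had 0.08 and 0.22. Among synapse and axon genes (camera adjusted p = 0.142 over 27 genes), NLGN4X (-1.51 and -0.46) and MAP2 (-0.62 and -0.37) fell in limma adjusted over the list alone, with 0 over all genes. INA had -1.03 and -0.19. NEFL had -0.76 in Lu139 and was below the expression limit in NCI-H209. Of the Notch pathway (camera adjusted p = 0.3 over 20 genes), DLK1 (0.70 and 0.31), LFNG (0.33 and 0.48) and JAG2 (0.33 and 0.35) rose in limma adjusted over the list alone, with 0 over all genes.

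The lists of the tuft-like and non-neuroendocrine forms of this cancer did not pass (camera adjusted p = 0.405 for each), and POU2F3 and YAP1 were themselves below the expression limit. PLCG2 passed upward in limma adjusted over the tuft list alone, with 0 genes over all genes, with 0.34 in NCI-H209. In Lu139 it was at 28.9 on the control array, under the expression limit, and at 47.5 after siTTF-1. Of the non-neuroendocrine list, LGALS3 had 0.73 and S100A11 0.75 in NCI-H209, and both were below the expression limit in Lu139. In the same list AMOTL2 had -0.33 and -0.21 and PLAU 0.52 and -0.01. The list's median was -0.03 in NCI-H209 and 0.15 in Lu139. A list made mostly of neuronal transcription factors had a camera adjusted p of 0.578.

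Anti-apoptotic BCL2 family genes did not pass as a list (camera adjusted p = 0.502 over 4 genes). BCL2 had log2 fold changes of -0.28 in NCI-H209 and -0.26 in Lu139 (mean -0.27, SD 0.014, n = 2 lines; limma adjusted p = 0.236 over all genes), BCL2L1 had 0.17 and -0.07, and MCL1 -0.09 and 0.04. The pro-apoptotic list had a camera adjusted p of 0.405 over 13 genes, and its members went both ways. BOK had 0.99 in NCI-H209, higher on 1 of its 2 probe sets, and was below the expression limit in Lu139. BNIP3 (-0.93 and -0.27) and BNIP3L (-0.47 and -0.36), receptors of mitophagy, fell in limma adjusted over the list alone, while the BH3-only genes BCL2L11 (0.68 and 0.33), HRK (0.45 and 0.31) and BMF (0.55 and 0.18) rose, against 0 over all genes. The caspases and death receptors had a camera adjusted p of 0.655 over 19 genes. Of these, BIRC5 and TNFRSF1A (-0.69 and -0.39) fell in limma adjusted over the list alone, with 0 over all genes. APAF1 had -0.41 and -0.20, lower on 1 of its 3 probe sets in each line, and XIAP -0.38 and -0.16.

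CDKN1A rose in limma adjusted over the list of cyclins and their kinases and inhibitors alone, as did GADD45A (0.54 and 0.28), while the retinoblastoma-related gene RBL1 fell (-0.39 and -0.38). That list did not pass as a whole (camera adjusted p = 0.542 over 24 genes), and 0 of its genes passed over all genes. Targets of p53 did not pass either (camera adjusted p = 0.542 over 19 genes). Among them CDKN1A, the stress cytokine gene GDF15 (1.17 and 0.30) and SPATA18 (0.26 in NCI-H209 and 0.43 in Lu139, where its mean was below the expression limit) rose and RRM2B (-0.66 and -0.30) and ZMAT3 (-0.25 and -0.52) fell in limma adjusted over the list alone, with 0 over all genes. MDM2 had 0.21 and 0.13, and BAX -0.14 and -0.04. MYC had 0.00 in Lu139 and was below the expression limit in NCI-H209, MYCL had -0.19 and 0.22 and MYCN 0.17 and 0.21. The list of the MYC family and its targets had a camera adjusted p of 0.596, with PA2G4 at -0.79 and -0.25.

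The remaining lists did not pass camera. Cholesterol synthesis and SREBP targets (adjusted p = 0.0527), MHC class I genes (adjusted p = 0.0535) and epithelial adhesion genes (adjusted p = 0.0539) came closest, each upward. They passed under some alternatives with the preset correlation, the cholesterol list under 6 (adjusted p 0.00762 to 0.0428), the MHC class I list under 4 (0.00475 to 0.0474) and the epithelial list under 4 (0.0142 to 0.0474), and none passed with an estimated correlation (adjusted p = 0.738 for each). STARD4 had -0.66 and -0.11, DHCR7 0.27 and 0.28, PSMB10 0.44 and 0.30, and CLDN4 0.76 and 0.08. Camera adjusted p was 0.405 for the type I interferon response, where IRF7 had 0.57 and 0.26 and ISG15 0.38 and 0.35 (at 31.6 on the control array of Lu139, under the expression limit), and 0.502 for heat shock, where HSPB1 had 0.69 and 0.34. It was 0.405 for mesenchymal genes, where FN1 had -1.18 and -0.07, 0.953 for glycolysis and hypoxia, where PDK1 had -0.98 and -0.18, and 0.327 for ribosomal proteins. Wnt pathway genes had a camera adjusted p of 0.502 and TGF-beta and BMP targets one of 0.781. Markers of immune cells (camera adjusted p = 0.405) and of stromal cells (camera adjusted p = 0.327) did not pass as lists, and of the latter RGS5 (-0.89 and -0.44) fell in limma adjusted over the list alone, with 0 over all genes.

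The lines themselves differed widely in both siRNA arms. MYC had an intensity of 10030 and 10039 in Lu139 and of 10.6 and 11.9 in NCI-H209, below the expression limit, and was at least 180-fold higher in Lu139 (limma adjusted p = 1.47e-07). For this and the genes below, "at least" sets the mean log2(value + 18.7) of the brighter line against the expression limit in the dimmer one, where the probe set was not above that limit, and such bounds give no order of the genes. MYCL was the reverse of MYC and above the limit in both lines, at 8192 in control NCI-H209 and 260 in control Lu139 cells (log2 difference -4.68, SE 0.12). Also higher in Lu139 were the neural crest transcription factor gene PAX3 (at least 61.3-fold), the galanin gene GAL (at least 62-fold), CEP15 (at least 37.2-fold), the fatty acid-binding protein gene FABP5 (at least 41.8-fold), the cyclin gene CCND2 (at least 32.2-fold), ZNF738 (at least 28-fold), CETN3 (at least 23.2-fold) and TUSC1 (at least 19.2-fold), and TRAP1, measured above the limit in both lines (log2 difference 5.23). Lower in Lu139 were WDR72 (at least 67.7-fold), the selenoprotein gene SELENOP (at least 60.9-fold), EFR3A (at least 50.2-fold), the epithelial transcription factor gene EHF (at least 53.3-fold), CEACAM5 (at least 86.5-fold), the keratin gene KRT7 (at least 91.6-fold), AGR3 (at least 38.4-fold), QPCT (at least 45.1-fold) and the moesin gene MSN (at least 35.4-fold), and PEBP1, measured above the limit in both lines (log2 difference -6.45). The direction of each of these was the same after quantile normalization.

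Of the fixed genes, LMO3 (log2 difference 4.61), NCAM1 (1.21), BCL2 (1.15), FOXA1 (1.11) and NKX2-1 itself (0.63) were higher in Lu139, and FOXA2 (-1.95), INSM1 (-0.79) and CHGA (-0.73) were lower, in limma and with the same direction after quantile normalization. These average both siRNA arms, and for NKX2-1 the control arrays alone differed by 0.38 on 211024_s_at (intensity 596 in NCI-H209 and 780 in Lu139). On 210673_x_at the control arrays differed more, at 196 in NCI-H209 and 400 in Lu139. In total limma called 7527 genes lower and 2727 higher in Lu139 at an adjusted p under 0.05, so that 73.4% were lower. That split followed the scaling: the median gene was shifted by -0.28 on the log2 scale in the values as deposited, and after quantile normalization over the 4 arrays the shift was 0.04, with 4784 lower and 5357 higher genes (47.2% lower). Over 4-fold, 797 genes were lower and 214 higher as deposited, and 503 and 306 after quantile normalization. The arrays of a line appear to have been normalized together and apart from those of the other line, so line and normalization batch cannot be told apart for small differences.

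**Figure D4:**
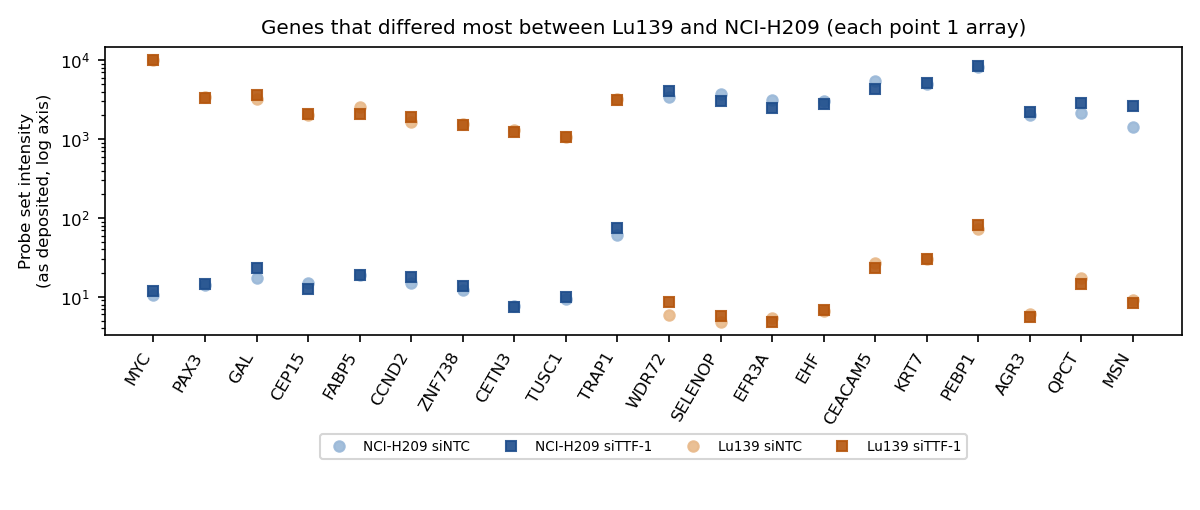
Linear probe set intensity on a log axis, as deposited, of the 10 genes with the highest and the 10 with the lowest log2 difference between Lu139 and NCI-H209, with each point 1 array and colours for line and siRNA. All but TRAP1 and PEBP1 were below the expression limit, an intensity of about 37.0, in the dimmer line. MYC was at 10.6 and 11.9 in NCI-H209 and at 10030 and 10039 in Lu139, and WDR72 was at least 67.7-fold lower in Lu139.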

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

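The tests of an interferon response, of noise in the NCI-H209 arrays and of the depth of the NKX2-1 knockdown were chosen after the result was seen, removal of each line's trend on mean signal was chosen after the data were seen, and the other tests named here before. Probe sets without a single gene symbol were not used in the comparisons above and also moved with siTTF-1. Of the 4485 such probe sets above the expression limit in both lines, 11 were at least 1.5-fold lower and 4 at least 1.5-fold higher in both, where independent lists would share 3.51 and 0.0548. The lowest was 226287_at, with a log2 fold change of -2.66 in NCI-H209 and -1.17 in Lu139. The probe set 231315_at had -0.89 and -0.76, 226580_at 1.48 and 0.70, and 227368_at 1.33 and 0.64. No biological explanation was tested for these, since their genes are not named here.

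The log2 fold changes of the 2 lines correlated across genes although the lines share no array. A signal-dependent shift on both siTTF-1 arrays could give such a correlation, but removal of each line's trend on mean signal left it at 0.504, with the trend fitted over the genes above the expression limit in both lines. Against a difference in RNA integrity, the mean 3' over 5' log2 ratio of GAPDH and actin differed between siTTF-1 and control by -0.0594 in NCI-H209 and by 0.00335 in Lu139. An interferon response to the siRNA stays open. The median of the interferon genes lay at percentile 71.2 of matched random lists in NCI-H209 and 47.1 in Lu139. Both were below the level written down as counting against such a response. That level took no account of members that go both ways. Of the 21 tested genes, 8 were higher and 4 lower in both lines, so the median was not taken to decide. A shared response to loss of TTF-1 and effects of the siRNA sequence on other transcripts, which both lines would share, were not tested and stay open.

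More genes passed 2-fold in NCI-H209 than in Lu139, a difference between lines that was not tested. Noise of the NCI-H209 arrays alone would leave about as many of its 95 lower genes above as below 0 in Lu139, but 88 of them (92.6%) were lower there. This tally includes genes below the expression limit in Lu139. Of the 85 above it, 82 (96.5%) were lower, with a median log2 fold change of -0.48. The tally does not show whether noise in NCI-H209 added to the number of genes past 2-fold, which stays open. Over genes above the expression limit in both lines, the ratio of the SDs of log2 values was 0.950 for Lu139 over NCI-H209. For these genes that argues against a narrower signal range in Lu139. Over all probe sets the quartiles were 17.5 and 189 on the control array of Lu139, against 19.5 and 263 on that of NCI-H209. A narrower range over all probe sets therefore stays open. A deeper knockdown in NCI-H209 could not be told apart from a line difference in response, because 1 of the 2 NKX2-1 probe sets had the larger decrease in NCI-H209 and the other in Lu139. A different response of the lines to the same loss may also contribute and stays open, untested.

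Mitosis genes were lower as a list after siTTF-1. A shift that lowers all abundant transcripts is argued against by the list's percentile among random lists matched on mean signal, 0.19 in NCI-H209 and 0.01 in Lu139. Whether the pattern depends on the probe set read for each gene stays open. Of the 35 other probe sets of 21 of these genes, 17 (48.6%) were lower in both lines, with medians of -0.02 in NCI-H209 and -0.15 in Lu139, although the mean of all probe sets per gene kept the list past the threshold (camera adjusted p = 5.15e-06 with the preset correlation, while an estimated correlation gave the list an adjusted p of 0.738). An effect of TTF-1 loss on the cell cycle was not tested and stays open.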

How the results depend on the processing

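Quantile normalization within each line, removal of the trend on mean signal and median centring were chosen after the data were seen. A count was taken as the same within 1.5-fold, and the NKX2-1 fold change within the SD over its 2 probe sets. The correlation was taken as the same within its 95% confidence interval over genes. A gene or list value was the same where its sign and its call held, whatever its size. For the siRNA effect 0 genes passed in the main setting, so none of those could lose a call. Of 153 recomputed main values 116 stayed the same. Of 1107 gene values 1010 stayed the same and 95 passed the threshold in addition. Of 117 list values 88 stayed the same, 15 lost and 14 gained a call, the 14 in the cholesterol, MHC class I and epithelial lists. The cause of the other changes was not tested. Genes 2-fold lower in Lu139 numbered 10 with the halved pseudocount. Doubling it left 0 genes 2-fold higher in Lu139 and 0 in both lines, and turned BCL2L2 to -0.000534. Quantile normalization over the 4 arrays gave 2 genes 2-fold higher in Lu139 and 2 in both lines, limma calls of 93 lower and 32 higher, a correlation of 0.502, and 4784 lower and 5357 higher genes in Lu139 against NCI-H209. Cyclic loess gave 5128 lower and 4807 higher in Lu139 (51.6% lower). The mean of all probe sets gave 43 lower and 13 higher genes in NCI-H209, 3 lower in Lu139 and turned MCL1 to 0.0176. The correlation was 0.534 without _x_at probe sets and 0.457 with no expression limit. A limit at the 60th percentile, which tests fewer genes, gave 32 lower and 6 higher calls and a correlation of 0.562. A threshold of 0.1 gave 39 and 8. At 1.5-fold there were 515 lower and 159 higher genes in NCI-H209, 131 and 27 in Lu139, and 50 and 6 in both. With an estimated correlation 0 of the 6 lists passed camera, a setting that rests on 1 residual degree of freedom and cannot decide. Trend removal, fitted here over all tested genes, gave 33 lower and 5 higher calls and a correlation of 0.505. Quantile normalization within each line gave 33 and 8 calls, 2 genes 2-fold higher in Lu139 and 2 in both. Centring gave 4092 lower and 6889 higher genes in Lu139 (37.3% lower). With no replicate block, that is no line term, limma called 0 genes (20 at an unadjusted p under 0.05, smallest adjusted p 1), since the line differences then enter the spread, and camera lost the immediate early (adjusted p = 0.18) and oxidative phosphorylation lists (0.364) and no other call. Over the alternatives with the preset correlation, the mitosis, DNA replication, histone and unfolded protein lists passed camera in each. Leaving out a line leaves no residual degree of freedom, so the values per line stand for it. Dim genes are limited by the background: a gene near an intensity of 37.0 has a compressed fold change.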

Other observations

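The test of antioxidant genes named here was chosen before its result was seen, after AKR1C1, AKR1C2, AKR1C3 and HMOX1 had been noticed. The genes in this paragraph were picked after their values were seen. HMOX1, the haem oxygenase gene, had log2 fold changes of 1.29 in NCI-H209 and 0.41 in Lu139, NQO1, a quinone reductase gene whose 3 probe sets were all higher in both lines, had 0.87 and 0.39, and SRXN1, the sulfiredoxin gene, had 0.57 and 0.39. The aldo-keto reductase genes had 0.39 and 0.90 (AKR1C1), 0.38 and 0.96 (AKR1C2) and 0.56 and 0.78 (AKR1C3). None of these passed limma with Benjamini-Hochberg adjustment over all genes, with an adjusted p of 0.143 for HMOX1 and 0.115 for NQO1.

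A candidate explanation is that targets of NRF2, the transcription factor of the antioxidant response, were higher as a set. Over 25 other NRF2 targets, the median log2 fold change was 0.14 in NCI-H209 and 0.11 in Lu139, at percentile 99.9 of matched random lists in NCI-H209 and 99.52 in Lu139, beyond the level set in advance for the set to count as higher in both. These percentiles describe the arrays. By the test used for the fixed lists, chosen here after the percentiles were seen, the set rose with the preset correlation (camera adjusted p = 0.0032 over 33 lists). The set did not pass with an estimated correlation (camera adjusted p = 0.733), which rests on 1 residual degree of freedom and cannot decide. Members of the set differed, with TXNRD1 at 0.05 and 0.23, GCLM at 0.07 and 0.10, and SLC7A11, which is also in the ATF4 list, at 0.49 and -0.07. Both arms received siRNA, and the arrays do not separate an effect of TTF-1 loss from one of the TTF-1 siRNA's sequence on other transcripts.

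Of 198 named genes compared between the lines, 26 had fold changes of opposite sign, and 0 were opposite by at least 1.2-fold in both lines.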
